A study of Mus musculus with 8 samples.

How the data were processed

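Poly(A) RNA of mouse ICF cells was sequenced on an Illumina HiSeq instrument in 8 libraries, 4 of cells cultured alone and 4 of cells cultured with Giardia lamblia. Groups and replicate numbers came from the sample labels. Per the submitters' processing notes, bcl2fastq 1.8.4, HISAT2 2.1.0, StringTie 1.3.4d and Cufflinks were used with the mouse build mm10, and the notes give no order or settings. The labels name a stranded and a second TruSeq kit, and the use of strand in counting is not given in the sources used here. Values of overlapping and antisense genes are therefore uncertain. The extraction text in the labels names human cells, while the organism label and the gene names are those of mouse.

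The deposited table holds read counts per gene for each library, per the file headers, and these whole-number counts were used as deposited. It also holds FPKM values per gene, normalized by the authors, per the file headers. FPKM per read followed the inverse of the library total within 1.05% across 9758 genes with over 200 reads in all libraries. Of low counts between 1 and 19, 43.7% were odd, so many were even, as when both mates of a pair are counted. The table has 24532 genes, of which 5549 had 0 reads in every library. Genes with FPKM of at least 1 in at least 4 of the 8 libraries were tested, which left 12168.

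The design fixed before the data were examined assumed FPKM alone, with limma on log2(FPKM + 1). Because the table also holds counts, the main gene test is edgeR's quasi-likelihood test on the counts, two-sided, with trimmed-mean (TMM) scaling, robust dispersion and Benjamini-Hochberg adjustment (threshold 0.05). The limma fit is given as an alternative. The standard error of a log2 fold change is its size over the square root of F. Reads are not independent molecules, so floors of 3 counts per library cover counting error only. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

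Gene lists were fixed before the data were examined: 33 lists with at least 5 tested members, on cell types, cytokines, stress and metabolism. Each was tested with limma's camera on log2(FPKM + 1) with an inter-gene correlation of 0.01, two-sided, with adjustment over the lists, and again with an estimated correlation and with limma's fry. Some genes stand in 2 or more lists, among them Il6, Arg1, Bst2, Hspa5 and Cxcl5. Named genes followed a rule fixed at the same time. It takes the 8 largest rises and the 8 largest falls among genes past the threshold, with no overlap between groups and a mean FPKM of at least 2, without predicted gene models. It adds 16 genes of type 1, 2 and 17 immunity, up to 4 members per list called by camera or with at least 3 members past the threshold, and the most abundant member of each cell type list. This gave 138 genes, and 2 of them were taken out of the report after writing and are not reported here. The receptor genes Il1rl1, Il17rb, Nmur1, Il2ra, Klrg1, Cxcr4 and Il9r fall outside the rule and were named after their values were seen, as were Ankrd37, Egln3 and Hk2. Symbols were matched by gene ID to the RefSeq annotation of GRCm38.p6, the build named mm10, from which coordinates (1-based) come.

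The replicate numbers in the titles were checked for pairing. Deviations from the group means correlated by 0.47, 0.30, 0.32 and 0.47 for numbers 1 to 4, and every library correlated best with the library of its own number, so the numbers were taken as pairs. The design has no block, and a fit with the number as a block is given where it changes a call or moves a count by over 1.5 times. The lowest chi-square per degree of freedom between libraries of a group was 94.0, so no library was a copy of another.

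The edgeR step was tested on simulated counts for the comparison of incubated with control libraries, with 200 changed genes among 12168. It recovered 1.5% of 67 genes changed by 0.5 on the log2 scale, 55.2% of 67 changed by 1 and 89.4% of 66 changed by 2. It made 103 calls, of which 6 were false, and 0 calls without changed genes. The set test called the moved list and 0 of 32 unmoved lists. Its simulated genes were drawn independently, so false calls from correlated genes could not show. In the data the estimated correlation within the ribosomal protein list was 0.83. Alternatives were pseudocounts of 0.1 and 0.5, 2 other filters, other scalings, limma variants, DESeq2, halved counts, the block and leaving out each library. All regroupings of the libraries into 4 and 4 were run as well.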

Results

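Gene expression was measured by sequencing of poly(A) RNA in mouse lamina propria cells, the immune cells that lie beneath the gut epithelium. The cells came from a fraction that contains innate lymphoid cells (ILCs), abbreviated ICF in the labels. Cells of 4 libraries were cultured alone (controls) and cells of 4 libraries were cultured with Giardia lamblia, a protozoan parasite of the small intestine, at a multiplicity of infection of 5. Cultures lasted 6 h in plates with transwell membranes. The labels number the replicates 1 to 4 in each group and do not say whether they came from separate animals, so p-values measure the spread between these samples, which may be technical. Total counts were 41631451, 42268772, 50798542 and 46630780 reads in control libraries 1 to 4. They were 41435262, 40609741, 43039077 and 34312890 reads in incubated libraries 1 to 4. Genes with at least 1 read numbered 16592 to 17042 per library.

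Incubation with Giardia went with a broad change in transcripts. Of 12168 genes tested, 1730 rose and 1452 fell in the incubated libraries (edgeR quasi-likelihood test, adjusted p threshold of 0.05, n = 4 per group). Changes of at least 2-fold were called for 873 rising and 576 falling genes. The 4 incubated and 4 control FPKM values did not overlap for 26.8% of tested genes, against 2.86% from chance when the pairing is left aside. With the replicate number as a block, the count of changed genes went from 3182 to 5011. On library totals alone, without trimmed-mean scaling, 2035 genes rose and 957 fell, and the median gene lay 0.12 above 0 on the log2 scale instead of 0.01. Directions of edgeR log2 fold changes below are relative to the trimmed-mean scaling. Camera and fry used log2(FPKM + 1) without that scaling, where the median gene lay 0.12 above 0. Fry does not compare a list with other genes, so its directions include that shift.

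The first principal component held 58.0% of the variance and parted the groups. Control library 4 scored -13.7 on it, between the other controls (-62.8 to -46.8) and the incubated libraries (41.7 to 46.3). Its Pearson correlation across genes was 0.95 with incubated library 4 and 0.95 to 0.96 with the other controls. Without it 4454 genes were called. The count was 2096 without control library 1, 1714 without control library 2 and 1978 without control library 3. Without both libraries numbered 4, an alternative chosen after seeing the data, it was 4267. Precursor ribosomal RNA (Rn45s) took 0.24 to 0.31% of reads in control libraries 1 to 3, 0.11% in control library 4 and 0.067 to 0.11% in the incubated libraries.

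**Figure D1:**
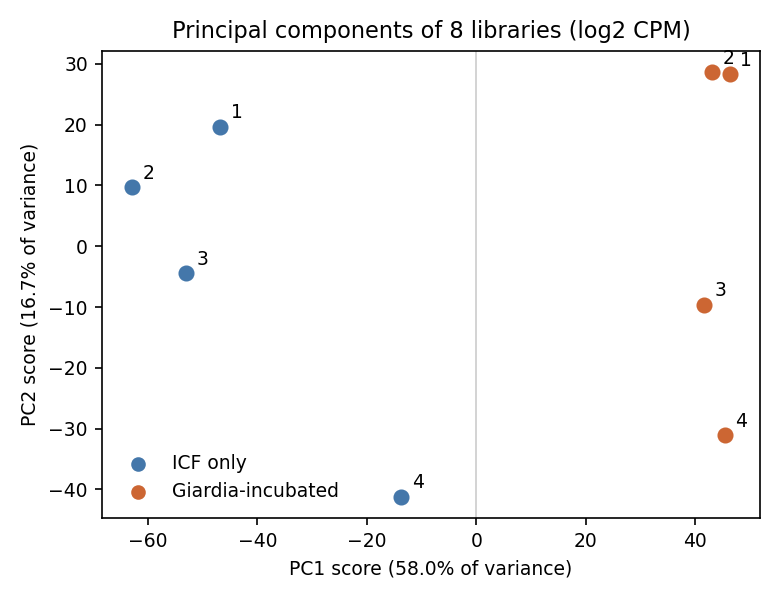
Scores of the 8 libraries on the first (x axis, 58.0% of variance) and second (y axis, 16.7%) principal components of log2 CPM (counts scaled to library size), with replicate numbers beside the points. The incubated libraries lie between 41.7 and 46.3 on the first component and control library 4 lies at -13.7, nearest to them of the controls.

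The series title names interleukin-17 production, so the transcripts of that pathway come first. RNA after 6 h does not measure secreted protein, and protein data were not used here. Il17a (gene ID 16171, GRCm38 chromosome 1, 20730905 to 20734496), which encodes interleukin-17A, stood at 8.42 ± 4.94 FPKM in controls and 10.2 ± 12 in incubated libraries (SD, n = 4 each). Its log2 fold change of 0.13 ± 0.75 (SE) did not pass the test (edgeR adjusted p = 0.91). Il17f (gene ID 257630, chromosome 1, 20777146 to 20785274) stood at 12.1 ± 5.27 and 8.36 ± 10.6 FPKM, with a log2 fold change of -0.68 ± 0.76 (edgeR adjusted p = 0.53). Incubated library 1 set both incubated means: its Il17a was 28.2 FPKM against 3.45 to 5.54 in the other 3. Without that library the log2 fold change of Il17a was -1.16 (edgeR adjusted p = 0.13) and that of Il17f was -2.13 (edgeR adjusted p = 0.014).

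Il22 (gene ID 50929, chromosome 10, 118204584 to 118210047), a cytokine acting on the gut epithelium, rose by 2.39 ± 0.71 on the log2 scale (edgeR adjusted p = 0.039), from 37.0 ± 14.9 to 207 ± 246 FPKM. Incubated library 1 held 576 FPKM of Il22, and without it the rise was 1.08 (edgeR adjusted p = 0.028). The Il22 call was lost in 6 of 22 alternatives. These were without control library 1, 2 or 3 (edgeR adjusted p = 0.092, 0.094 and 0.096), with the replicate number as a block (log2 fold change 1.69, edgeR adjusted p = 0.092), with no filter on low values (edgeR adjusted p = 0.051) and with limma after quantile normalization (adjusted p = 0.0503). Il23r, the receptor for interleukin-23, fell by 1.56 ± 0.23 (edgeR adjusted p = 0.0023).

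Of 23 tested ILC3 and type 17 genes, 2 rose and 6 fell, the same counts when adjusted over the list alone. The riser besides Il22 was Lta (lymphotoxin alpha, 1.86 ± 0.27), and Maf (-1.56 ± 0.26) and the receptor tyrosine kinase Kit (-0.76 ± 0.14) were among those that fell. The list did not pass the set test (camera adjusted p = 0.084). It passed, downward, in 4 of 22 alternatives (adjusted p = 0.014 to 0.84 over them), among them without control library 4 (0.037) and without incubated library 1 (0.014), with adjusted p = 0.84 with an estimated correlation. Of 17 tested interleukin-17 target genes, 2 rose and 3 fell, and 5 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.87). With the block, 5 rose and 4 fell. The neutrophil chemokine gene Cxcl5 rose by 4.41 ± 0.73 and the matrix metalloproteinase gene Mmp3 by 4.61 ± 1.10. Without control library 4 these rises were 5.09 and 6.33, and without incubated library 1 that of Mmp3 was 3.86. Nfkbiz fell by 0.66 ± 0.15.

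**Figure D2:**
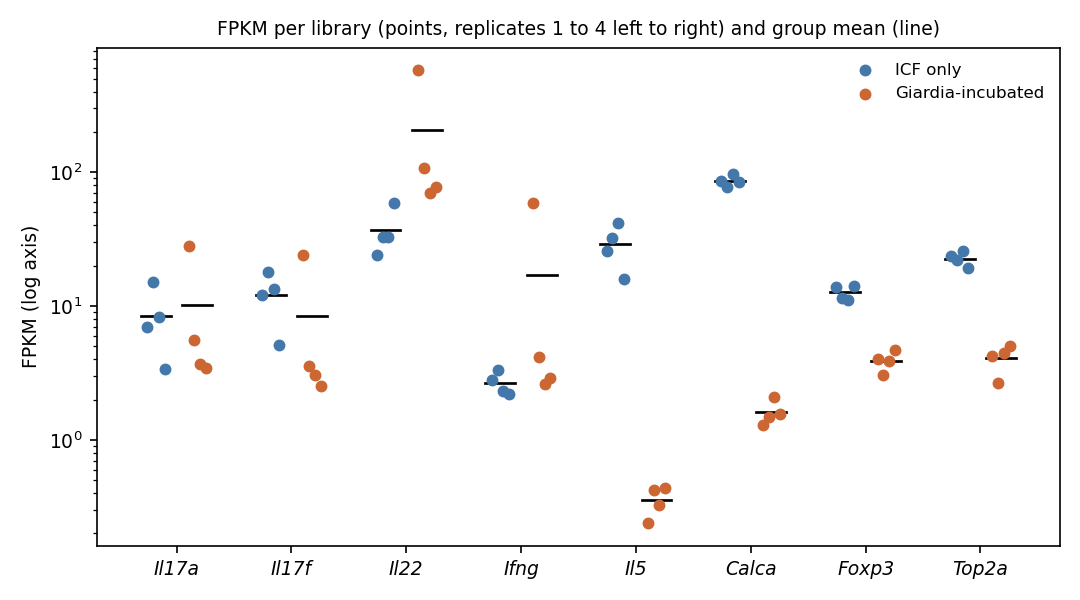
FPKM (y axis, log scale) of 8 genes in each library, with 4 control points and 4 incubated points per gene in replicate order and a line at each group mean. Il17a, Il17f, Il22 and Ifng stand apart in incubated library 1 (28.2 FPKM for Il17a), while Il5, Calca, Foxp3 and Top2a are lower in all 4 incubated libraries than in all 4 controls.

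Among genes past the threshold with no overlap between groups and a mean FPKM of at least 2, predicted gene models aside, the 2 deepest falls were in Il5 and Calca, both of the ILC2 and type 2 list. Il5 (gene ID 16191, chromosome 11, 53720794 to 53725103), the cytokine that sustains eosinophils, fell from 29.0 ± 10.9 to 0.357 ± 0.0935 FPKM (log2 fold change -6.46 ± 0.40, edgeR adjusted p = 0.00011). Calca (gene ID 12310, chromosome 7, 114625981 to 114636910), which encodes the neuropeptide CGRP, fell from 86.0 ± 8.0 to 1.61 ± 0.344 FPKM (-5.86 ± 0.19, edgeR adjusted p = 1.2e-06). Incubated libraries held 16 to 28 reads of Il5, so its level there carries a wide counting error. Of 20 tested ILC2 and type 2 genes, 10 fell and 1 rose, and 12 fell and 1 rose when adjusted over the list alone (12 fell and 2 rose with the block). The type 2 transcription factor gene Gata3 fell by 1.11 ± 0.17 and the costimulatory receptor gene Icos by 1.75 ± 0.25, while arginase gene Arg1 rose by 2.14 ± 0.42. Of its other receptor genes, Klrg1 (-1.48 ± 0.22), Cxcr4 (-1.89 ± 0.32) and Il9r (-1.09 ± 0.33) fell, and Il1rl1 (0.47 ± 0.43), Il17rb (-0.58 ± 0.26), Nmur1 (-0.28 ± 0.38) and Il2ra (0.27 ± 0.22) did not pass. The list was called downward by camera (adjusted p = 1.3e-05), with adjusted p = 0.12 with an estimated correlation. Il13 was lower in incubated libraries without passing (-2.05 ± 0.75, edgeR adjusted p = 0.07), but it passed in 11 of 22 alternatives (adjusted p = 0.0046 to 0.15 over them). Among these were the block (-2.30, edgeR adjusted p = 0.016), DESeq2 (-2.08, adjusted p = 0.03), limma on log2(FPKM + 1) (-0.94, adjusted p = 0.021) and the 6 other limma fits (adjusted p = 0.0046 to 0.043). It also passed without incubated library 4 (-1.66, edgeR adjusted p = 0.035) and without both libraries numbered 4 (-1.88, edgeR adjusted p = 0.011).

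Among 12 eosinophil, basophil and mast cell markers, 3 fell and 1 rose, over all genes and over the list alone (camera adjusted p = 0.11), and 4 fell and 4 rose with the block. The set test passed, downward, in 4 of 21 alternatives, among them without control library 3 (adjusted p = 0.045), control library 4 (0.042) or incubated library 1 (0.03), with adjusted p = 0.84 with an estimated correlation. The directional fry test, which does not compare a list with other genes, gave adjusted p = 0.04 with the block and 0.28 without it. The mast cell protease gene Mcpt1 fell by 5.34 ± 0.86 and the eosinophil granule gene Prg2 by 3.85 ± 0.45. Without incubated library 1 the fall of Mcpt1 was -6.93 on that scale. Alox15, a lipoxygenase gene and the most abundant of these markers, rose by 3.09 ± 0.95, from 12.4 ± 13.1 to 114 ± 108 FPKM (edgeR adjusted p = 0.042, and 0.0017 with the block). Its call was lost in 8 of 23 alternatives (adjusted p = 0.052 to 0.11), among them without control library 2, 3 or 4 and without incubated library 1 or 2, and its value was 4.11 without control library 1 and 2.26 without incubated library 1. Other genes with large falls included Fosb (-4.87 ± 0.37), Gzmc (-4.0 ± 0.61) and Retnla (-4.03 ± 1.03). Incubated libraries held 0 to 32 reads of Mcpt1, 8 to 26 of Prg2 and 0 to 29 of Retnla. The sizes of these 3 falls therefore carry a wide counting error. The Retnla call was lost without control library 1 or 2 and without incubated library 1 or 3 (edgeR adjusted p = 0.05 to 0.054). The value of Gzmc was -4.76 without incubated library 1. Mcpt1, Mcpt2 and Gzmc have near copies in their clusters, and the sharing of reads between them is uncertain.

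Cytotoxic and type 1 transcripts fell in part. Of 21 tested ILC1, NK and type 1 genes, 7 fell and 1 rose, over all genes and over the list alone. Granzyme genes Gzma and Gzmb fell by 3.28 ± 0.64 and 3.39 ± 0.81, and the interleukin-12 receptor gene Il12rb2 fell by 2.19 ± 0.50. Without incubated library 1 the log2 fold changes of these 3 genes were -4.09, -4.10 and -2.86. Ifng, which encodes interferon gamma, stood at 2.68 ± 0.524 and 17.1 ± 27.7 FPKM and did not pass (2.54 ± 1.03, edgeR adjusted p = 0.097). Incubated library 1 held 58.7 FPKM of Ifng, and without it the log2 fold change was 0.13. The list was called downward by camera (adjusted p = 0.0078), with adjusted p = 0.84 with an estimated correlation.

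Regulatory transcripts fell in large part. Foxp3 (chromosome X, 7579676 to 7595243), the transcription factor of regulatory T cells, went from 12.6 ± 1.65 to 3.92 ± 0.676 FPKM (-1.81 ± 0.15, edgeR adjusted p = 0.00029). Inhibitory receptor genes Ctla4 (-2.95 ± 0.31), Havcr2 (-2.95 ± 0.34) and Tigit (-2.66 ± 0.19) fell as well. Of 16 tested regulatory cytokines and receptors, 8 fell and 2 rose, and 8 fell and 3 rose over the list alone (camera adjusted p = 0.00017; adjusted p = 0.29 with an estimated correlation). Of 18 T cell markers, 3 fell and 0 rose, over all genes and over the list alone, and 7 fell and 3 rose with the block. Cd3g had a log2 fold change of -0.06 ± 0.28. That list did not pass (camera adjusted p = 0.11), but it passed, downward, in 3 of 22 alternatives, among them without control library 3 (adjusted p = 0.038) and without incubated library 4 (0.00084). It had adjusted p = 0.84 with an estimated correlation and 0.66 by fry.

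Cell cycle transcripts fell almost throughout. Of 30 tested cell cycle genes, 29 fell and 0 rose, over all genes and over the list alone, with a median log2 fold change of -1.98. Top2a (gene ID 21973, chromosome 11, 98992947 to 99024199), a topoisomerase of dividing cells, went from 22.6 ± 2.69 to 4.11 ± 1.01 FPKM (-2.59 ± 0.21, edgeR adjusted p = 0.00029). The mitotic kinesin gene Kif11 fell by 3.01 ± 0.25 and the cyclin gene Ccna2 by 2.81 ± 0.25. The list was called downward by camera (adjusted p = 1.2e-26), with adjusted p = 0.12 with an estimated correlation.

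Immediate early and stress genes also fell in part. Of 27 tested immediate early and tissue dissociation genes, 13 fell and 1 rose, and 15 fell and 1 rose over the list alone (16 fell and 2 rose with the block). The transcription factor genes Fos (-2.57 ± 0.36), Nr4a1 (-2.31 ± 0.19) and Nr4a2 (-1.52 ± 0.19) were among them (camera adjusted p = 3.5e-06; adjusted p = 0.17 with an estimated correlation). Of 20 unfolded protein response genes, 8 fell and 0 rose, 12 fell over the list alone and 13 fell with the block, with the stress sensor gene Ern1 at -2.21 ± 0.25 and the chaperone gene Hspa5 at -0.92 ± 0.15 (camera adjusted p = 1.3e-05; adjusted p = 0.17 with an estimated correlation). Of 19 heat shock and protein folding genes, 6 fell and 1 rose, and 7 fell and 1 rose over the list alone (camera adjusted p = 0.011; adjusted p = 0.82 with an estimated correlation). With the block 8 fell and 2 rose, and the call was lost after quantile normalization (adjusted p = 0.18). Hspa1a (-3.19 ± 0.38) and Hspa1b (-3.07 ± 0.37) are near-identical copies that can share reads. Of 29 amino acid starvation and integrated stress response genes, 5 fell and 1 rose, and 5 fell and 0 rose over the list alone (camera adjusted p = 0.084), with Cars at -0.83 ± 0.18 and Ddit4 at -0.78 ± 0.18. That list passed, downward, without control library 1 (adjusted p = 0.025) and without incubated library 1 or 2 (0.019 and 0.024), with adjusted p = 0.84 with an estimated correlation.

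**Figure D3:**
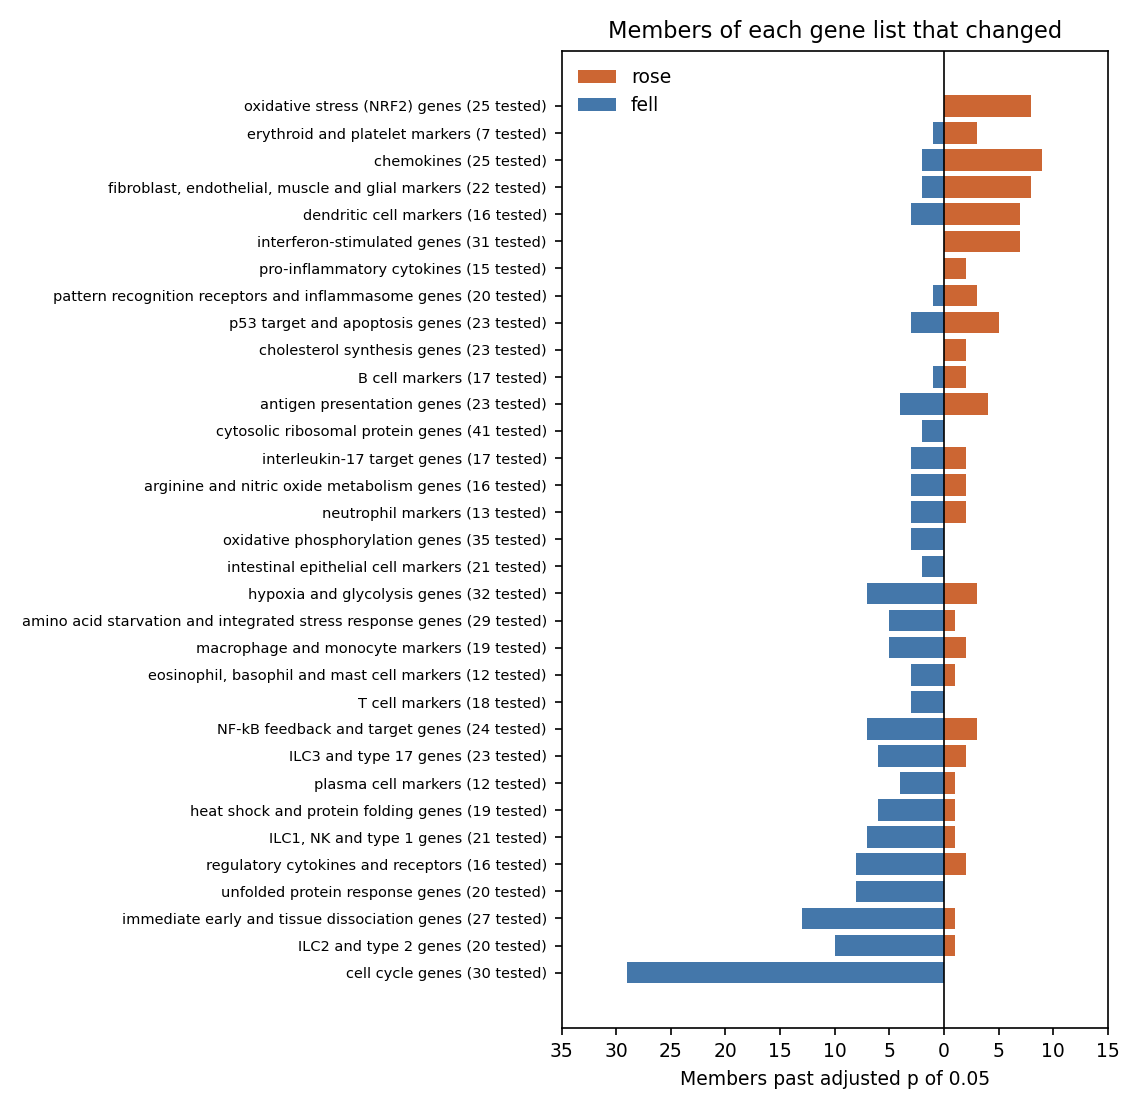
Number of members (x axis) of each gene list that fell (bars to the left) or rose (bars to the right) past the edgeR adjusted p threshold of 0.05, with the number tested beside each name. The cell cycle list, with 29 of 30 members down, stands at the lower end, and the oxidative stress list, with 8 of 25 members up, at the upper end.

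Some antiviral and antioxidant transcripts rose. Of 31 interferon-stimulated genes, 7 rose and 0 fell, 5 rose over the list alone and 19 rose with the block, including Oasl2 (2.04 ± 0.40), Oas2 (2.71 ± 0.62) and Bst2 (1.62 ± 0.37). Of 25 oxidative stress (NRF2) genes, 8 rose and 0 fell, over all genes and over the list alone, and 8 rose and 2 fell with the block. They included Gclm, which encodes a subunit of the enzyme that starts glutathione synthesis (1.41 ± 0.19), Me1 (1.77 ± 0.25) and the glutathione transferase genes Gsta3 (4.05 ± 0.58) and Gsta4 (3.77 ± 0.57), members of a family whose reads may be shared. Gsta4 stood at 4.41 without control library 4. Camera called both lists upward (adjusted p = 0.011 each), with adjusted p = 0.84 for each with an estimated correlation. With the block the interferon list had camera adjusted p = 8.6e-06 and adjusted p = 0.67 with an estimated correlation, and the directional fry test gave adjusted p = 0.02 with the block and 0.34 without it. The interferon call was lost without control library 2 (adjusted p = 0.052), without incubated library 1 (0.096), without both libraries numbered 4 (0.1) and with array weights (0.053), and the antioxidant call without incubated library 2 (0.059). Of 32 hypoxia and glycolysis genes, 3 rose and 7 fell, and 3 rose and 12 fell over the list alone (camera adjusted p = 0.084). With the block 4 rose and 12 fell and camera gave adjusted p = 0.033, with adjusted p = 0.82 with an estimated correlation. The list passed, downward, in 4 of 22 alternatives, the others being without control library 4 (adjusted p = 0.00052), without both libraries numbered 4 (0.00044) and with array weights (0.0031). The 3 risers were Pfkfb3 (2.14 ± 0.20), a regulator of glycolysis, Adm (1.78 ± 0.21) and P4ha2 (1.22 ± 0.26), and those that fell included Ankrd37 (-3.19 ± 0.70), Egln3 (-1.61 ± 0.35) and the glycolytic enzyme gene Hk2 (-1.08 ± 0.34). Of 16 arginine and nitric oxide metabolism genes, 2 rose and 3 fell, 2 rose and 5 fell over the list alone and 3 rose and 6 fell with the block (camera adjusted p = 0.38, downward like the median, while the mean lay the other way). That list passed with a mean FPKM of at least 5 (adjusted p = 0.048), with adjusted p = 0.84 with an estimated correlation. Arg1 and the arginine transporter gene Slc7a2 (3.99 ± 0.53, and 3.37 without incubated library 1) rose, and the polyamine synthesis gene Odc1 fell by 1.79 ± 0.27. Nos2 was below the filter, at 0.395 ± 0.0844 FPKM in controls and 0.453 ± 0.595 in incubated libraries.

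Chemokine genes mostly rose among those that passed. Of 25 tested, 9 rose and 2 fell, 10 rose and 2 fell over the list alone and 13 rose and 5 fell with the block (camera adjusted p = 0.22). The fry test gave that list adjusted p = 0.019 with the block and 0.16 without it. Camera with an estimated correlation gave it adjusted p = 0.78 with the block and 0.85 without it. Ccl17, which attracts T cells, went from 11.2 ± 5.21 to 151 ± 59.1 FPKM (3.66 ± 0.39, edgeR adjusted p = 0.00074), and Ccl9 rose by 2.37 ± 0.35. Of 15 pro-inflammatory cytokines, 2 rose and 0 fell, over all genes and over the list alone, and 4 rose and 2 fell with the block (camera adjusted p = 0.57). Il1b (-1.28 ± 0.52, edgeR adjusted p = 0.095), Il6 (0.69 ± 0.49, edgeR adjusted p = 0.32), Tnf (0.23 ± 0.43, edgeR adjusted p = 0.71) and Csf2 (0.97 ± 0.42, edgeR adjusted p = 0.11) did not pass. Csf2 passed in 3 of 23 alternatives, with the block (0.91, edgeR adjusted p = 0.035), without control library 4 (1.34, edgeR adjusted p = 0.037) and in limma with array weights (1.11, adjusted p = 0.035). Il1b passed in 4 of 23, without control library 4 (-1.62, edgeR adjusted p = 0.0025), without both libraries numbered 4 (-1.61, edgeR adjusted p = 0.0091), in DESeq2 (-1.29, adjusted p = 0.022) and in limma with array weights (-1.39, adjusted p = 0.021). Of 24 NF-kB feedback and target genes, 3 rose and 7 fell, over all genes and over the list alone (camera adjusted p = 0.2). The NF-kB inhibitor gene Tnfaip3 fell by 2.22 ± 0.28 and the costimulatory receptor gene Cd40 rose by 1.02 ± 0.23. Of 20 pattern recognition receptors and inflammasome genes, 3 rose and 1 fell, over all genes and over the list alone (camera adjusted p = 0.7). With the block 7 rose and 3 fell. Fry gave that list adjusted p = 0.019 with the block and 0.28 without it. With an estimated correlation camera gave adjusted p = 0.83 with the block and 0.94 without it.

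Dendritic cell markers moved apart. Of 16 tested, 7 rose and 3 fell, and 8 rose and 3 fell over the list alone (camera adjusted p = 0.19). The list passed, upward, with a mean FPKM of at least 5 (adjusted p = 0.036) and by the directional fry test (0.003), which does not compare a list with other genes. It had adjusted p = 0.75 with an estimated correlation. Fscn1, an actin-bundling gene of mature dendritic cells, went from 23.5 ± 19.7 to 285 ± 50.4 FPKM (3.52 ± 0.48, edgeR adjusted p = 0.0017). Flt3 and Batf3 rose by 2.40 ± 0.43 and 2.46 ± 0.47, and Mgl2 fell by 3.10 ± 0.60. Without control library 4 the rises of Fscn1, Flt3 and Batf3 were 4.21, 3.08 and 3.12. Of 23 antigen presentation genes, 4 rose and 4 fell, and 6 rose and 5 fell over the list alone (camera adjusted p = 0.7). The costimulatory gene Cd80 rose by 1.60 ± 0.24, and the class II gene H2-Aa went from 2230 ± 830 to 730 ± 364 FPKM (-1.76 ± 0.45, edgeR adjusted p = 0.021). The H2-Aa call was lost without control library 2 (edgeR adjusted p = 0.057), control library 3 (edgeR adjusted p = 0.056) or incubated library 1 (edgeR adjusted p = 0.052).

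Of 19 macrophage and monocyte markers, 2 rose and 5 fell, and 2 rose and 6 fell over the list alone (camera adjusted p = 0.056). With the block 4 rose and 10 fell and camera gave adjusted p = 0.016, with adjusted p = 0.67 with an estimated correlation. The list passed, downward, in 9 of 22 alternatives (adjusted p = 0.0029 to 0.84 over them), among them without control library 3 or 4 and without incubated library 1 (0.027, 0.0029 and 0.014). Apoe fell by 1.52 ± 0.35 and Timd4 by 2.45 ± 0.41, while the chemokine gene Pf4 rose by 2.34 ± 0.36. Of 13 neutrophil markers, 2 rose and 3 fell, 3 rose and 3 fell over the list alone and 3 rose and 7 fell with the block (camera adjusted p = 0.25), with the collagenase gene Mmp8 up by 5.82 ± 0.74 and the decoy receptor gene Il1r2 down (-3.05 ± 0.61). Mmp8 stood at 6.42 without control library 4 and 5.24 without incubated library 2. Of 12 plasma cell markers, 4 fell and 1 rose, 7 fell and 1 rose over the list alone, and 9 fell and 1 rose with the block. Jchain, the joining chain of secreted antibodies, went from 1055 ± 295 to 210 ± 145 FPKM (-2.45 ± 0.50, edgeR adjusted p = 0.0094), and Sdc1 fell by 1.81 ± 0.13. Camera called that list downward (adjusted p = 8.1e-05), with adjusted p = 0.34 with an estimated correlation. Of 17 B cell markers, 2 rose and 1 fell, over all genes and over the list alone, 4 rose and 2 fell with the block, and Cd79a had a log2 fold change of 0.26 ± 0.31 (camera adjusted p = 0.77).

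Of 22 fibroblast, endothelial, muscle and glial markers, 8 rose and 2 fell, 8 rose and 3 fell over the list alone, and 9 rose and 8 fell with the block. Camera gave adjusted p = 0.7, upward, while the median lay below 0. The mesenchymal receptor gene Pdgfra (2.86 ± 0.38) and the endothelial genes Vwf (1.72 ± 0.25) and Kdr (1.54 ± 0.28) were among the risers. Not every endothelial gene of the list passed. Of 21 intestinal epithelial cell markers, 2 fell over all genes and 0 over the list alone (camera adjusted p = 0.13), and Defa24 had a log2 fold change of -0.15 ± 0.43. With the block 2 rose and 5 fell and camera gave adjusted p = 0.033, with adjusted p = 0.78 with an estimated correlation. The list also passed, downward, without incubated library 2 (adjusted p = 0.0051) and with no filter on low values (0.033). Of 7 erythroid and platelet markers, 3 rose and 1 fell, over all genes and over the list alone (camera adjusted p = 0.8, downward, with the median above 0). The platelet gene Ppbp rose by 2.37 ± 0.44 and the globin gene Hbb-bt, which has a near-identical copy, fell by 2.12 ± 0.34.

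Of 41 cytosolic ribosomal protein genes, 2 fell and 0 rose over all genes, 1 fell with the block and 0 passed over the list alone. The calls of the 2, Rps2 (-0.53 ± 0.15) and Rpl10 (-0.40 ± 0.13), were lost in 6 and 18 of 23 alternatives. Camera called that list downward (adjusted p = 5e-05), with adjusted p = 0.84 with an estimated correlation and adjusted p = 0.88, upward, after quantile normalization. Of 35 oxidative phosphorylation genes, 3 fell over all genes and 0 over the list alone (camera adjusted p = 0.2, and 0.02 without control library 3; adjusted p = 0.94 with an estimated correlation). The calls of these 3, Cox6c (-0.48 ± 0.14), Ndufs1 (-0.39 ± 0.12) and Uqcrc1 (-0.36 ± 0.11), were lost in 15, 17 and 18 of 23 alternatives, limma on log2(FPKM + 1), library totals and upper-quartile scaling among them. Of 23 cholesterol synthesis genes, 2 rose over all genes, 4 with the block and 0 over the list alone (camera adjusted p = 0.7). Of 23 p53 target and apoptosis genes, 5 rose and 3 fell, over all genes and over the list alone, and 8 rose and 4 fell with the block (camera adjusted p = 0.23), with Phlda3 up by 2.80 ± 0.29 and the pro-apoptotic gene Bcl2l11 down (-1.26 ± 0.19).

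Genes outside the lists with large rises included U90926 (chromosome 5, 92209895 to 92215408), with 0 reads in all 4 controls and 31 to 220 reads in the incubated libraries. Against a floor of 3 counts per library its mean level was at least 35.2-fold higher, and at least 20.3-fold higher without incubated library 1. Hmga2, a chromatin architecture gene, rose by 5.75 ± 0.79, the sodium channel subunit gene Scn4b by 5.18 ± 0.97, Tmem150c by 4.40 ± 0.57 and Plek2 by 4.28 ± 0.51. Without control library 4 these values were 6.72, 7.6, 5.41 and 4.94.

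In total, 11 of 33 lists passed camera with its preset correlation of 0.01, 2 upward and 9 downward, and 0 passed with an estimated correlation. The directional fry test did not call 5 of the 11, those of ILC1, NK and type 1, interferon-stimulated, heat shock, antioxidant and ribosomal protein genes (adjusted p = 0.08 to 0.39). Of the 35 splits of the 8 libraries into 4 and 4, 28 gave 11 or more called lists, so the number of camera calls did not set the real grouping apart. The counts of single genes did: the real split gave 3182 and no other split gave more than 1. Only the cell cycle list and the ILC2 and type 2 list had their smallest camera p in the real split, a comparison chosen after seeing the data.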

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

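The tests of incubated library 1 and control library 4 in this part were chosen after their results, or values bearing on them, had been seen. The counts over regroupings of the libraries were planned before. A library was singled out when its gap to the nearest of the other 3 in its group took up most of the range of the group. Of 275 such groups of 4 values, 22 were singled out, and chance gives about 1 in 20 for normally distributed values. The rule was run on FPKM without a log scale, where a skew toward high values would raise that share.

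In incubated library 1, 9 genes stood above the other 3 incubated libraries: Il22 at 576 FPKM, Gzma at 89.1, Ifng at 58.7, Il18r1 at 48.8, Il17a at 28.2, Il17f at 24.3, Maf at 13.9, Ifi44 at 13 and Il23r at 3.37. The 4 cytokine genes Ifng, Il17a, Il17f and Il22 lay 2.77 to 4.20 above the mean of the others on the log2 scale. More T cells would raise T cell markers, whose median excess over 18 markers was -0.10 ± 0.07 (SE), which argues against that. A scaling error would raise all genes, and their median excess in the deposited FPKM was -0.0076. Those values were already scaled to library totals, which holds that median near 0. The value therefore speaks only against an error left after that scaling. T cell markers and markers of ILC1 and NK cells were first tested together (median excess 0.37 ± 0.16 over 38 markers, under the bound of 1.38) and were parted after that result was seen. The 20 markers of ILC1 and NK cells had a median excess of 1.08 ± 0.16, with 11 over 1, against a bound of 1.38. A larger share or a stronger activation of such cells stays open, and these cannot be told apart here. Of the 4 cytokine genes, only Ifng stands in the list those markers came from. Il17a, Il17f and Il22 stand in the ILC3 and type 17 list, as do Il23r and Maf. A larger share or a stronger activation of ILC3 and type 17 cells was not tested. Activation of T cells and a response of 1 culture to Giardia were not tested either.

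In control library 4, genes above the other 3 controls were Psme2 at 314 FPKM, Fscn1 at 52.8, Flt3 at 18.4, Mmp3 at 12.5, Gsta4 at 4.46, Ccl25 at 2.09, Scn4b at 0.855 and Tmem150c at 0.618, and Havcr2 was below them at 13.8. All of these lie toward the incubated level. An exchange of labels with an incubated library would put an incubated library among the controls, and 0 lay on the control side of the first principal component. RNA or cells of an incubated culture, if they alone set control library 4, would give 1 share for rising and falling genes. The implied share was 0.22 over 1124 rising genes and 0.61 over 709 falling genes. The difference was -0.39, with overlapping quartile ranges, against -0.07 to 0.04 for the other controls. With incubated library 4 as the source the shares were 0.26 and 0.61. Under the rule written for this test, overlapping quartile ranges decide nothing. A mixture as the whole account or as a part of it stays open. Calca (85.1 FPKM) stayed at control level in control library 4 and Il5 (16 FPKM) lay below the other controls. A mixture and a culture that differed from the start cannot be told apart with these values, since the mixture's source profile is assumed.

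Il5 and Calca had log2 fold changes of -6.46 ± 0.40 and -5.86 ± 0.19, while the median over all 20 tested members of the ILC2 list was -0.98 ± 0.57 (SE).

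Other single values were Ccl22 at 905 FPKM and S100a9 at 8.97 in incubated library 2, Sdc1 at 9.73 in incubated library 4 and Clec4d at 27.7 in control library 1.

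The real grouping gave 3182 changed genes and 1449 changed at least 2-fold, and 1 of the 35 splits into 4 and 4, the real split itself, reached each count. The highest of the other splits gave 1 gene in each case. These 35 splits leave the pairing aside, although the numbers were taken as pairs, so they cannot exclude chance regrouping for either count. Among the 8 splits that part all 4 numbered pairs the others gave 0, and 8 splits are too few for a share under 5%. The real split thus gave far more genes than any other, without a test that excludes chance. For the gene lists, 28 of 35 splits gave 11 or more, the highest other 21, so chance regrouping cannot be excluded for that count. Among the 8 pair-parting splits 7 gave as many lists.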

How the results depend on the processing

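The limma fit on log2(FPKM + 1) was the planned gene test, and edgeR on counts replaced it once the table was seen. That limma fit called 3183 genes, 2202 rising and 981 falling, with 1082 changed at least 2-fold. DESeq2, library totals, halved counts, camera on log2 CPM and leaving out both libraries numbered 4 were chosen after seeing the data. The count of 3182 changed genes became 1899 with a mean FPKM of at least 5 (fewer genes tested), 4991 with array weights, 5011 with the replicate block and 1640 at an unadjusted p under 0.05 with a 2-fold change; the cause was not tested for the array weights. Of the blocked calls, 3154 were shared with the 3182. Leaving out each library in turn gave 1714 to 4454, with 1714, 2096 and 1978 without control library 2, 1 and 3. The count of 1449 genes changed at least 2-fold became 681 with a mean FPKM of at least 5, and 1078 to 1864 with a library left out. The share of calls that rose was 54.4%, but 69.2% with limma on log2(FPKM + 1), 68.0% on library totals and 73.7% after rescaling FPKM to TPM, where the median gene moved by 0.12, 0.12 and 0.16. In shared calls 0 changed sign under the alternatives run. The 11 called lists became 0 with an estimated correlation and 7 with the directional fry test, which does not compare a list with other genes, and 10 to 15 with a library left out. The set difference of the ribosomal protein list (cytosolic ribosomal protein genes) was -0.099 after quantile normalization, where camera's direction turned upward; the cause was not tested.

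Over the settings that leave out no single library, 57 of 2026 named-gene results lost their call, in 12 genes, and 16 gained one, in 4 genes. With a library left out, 87 of 1096 lost it, in 21 genes, and 4 gained it; 0 named-gene calls reversed. The block ended the calls of Il22 and Rpl10, gave calls to Il13, Csf2 and, in camera, 3 lists, and changed no other edgeR call among the named genes or camera call among the lists. In fry it gave calls to the chemokine, pattern recognition, interferon-stimulated and eosinophil, basophil and mast cell lists (adjusted p = 0.019 to 0.04) and changed no other. DESeq2 gave no adjusted p for Il22 and Ifng. At this depth and spread the simulated test, with 200 changed genes, recovered 1.5% of those changed by 0.5 on the log2 scale. In the data 3182 genes passed, so the adjusted threshold was less strict and that share cannot be carried over. How many changes of that size went undetected was not tested.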

Other observations

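Other members of the dendritic cell, antigen presentation and cytokine lists changed with incubation. Ccr7, the receptor that guides dendritic cells to lymph nodes, rose by 0.57 ± 0.17 on the log2 scale, and the integrin gene Itgax fell by 2.36 ± 0.64. H2-Ab1 and H2-Eb1 fell by 1.72 ± 0.47 and 1.77 ± 0.48, while the immunoproteasome genes Psmb8 (0.88 ± 0.25) and Psmb9 (0.80 ± 0.22) rose. Il15, a cytokine that sustains NK cells and ILC1, rose by 2.39 ± 0.43, and Ebi3 rose by 1.03 ± 0.25. These genes were picked after their values were seen, with edgeR adjusted p = 0.0056 to 0.041. With the replicate number as a block their edgeR adjusted p was 0.0022 to 0.0498, and no other alternative is given for them.

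Markers of non-immune cells moved in both directions. The glial gene Sox10 rose by 2.52 ± 0.50 and the stromal gene Pdpn by 2.02 ± 0.40, while the collagen gene Col1a2 fell by 1.91 ± 0.53 and the muscle gene Myh11 by 1.32 ± 0.33. The epithelial genes Epcam and Olfm4 fell by 0.69 ± 0.21 and 1.81 ± 0.55. These genes too were picked after their values were seen, with edgeR adjusted p = 0.0082 to 0.04. With the block it was 0.001 to 0.019, and no other alternative is given for them.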
